A study of Homo sapiens with 18 samples.

How the data were processed

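RNA was measured in 18 libraries of HepG2 cells, a human hepatoblastoma-derived liver line, in 6 groups of 3: the vehicles DMSO and ethanol at 0.1% each, the small molecules 6N, 10CA and 6N-10CA at 10 µM each, and the phospholipid DLPC (dilauroylphosphatidylcholine) at 100 µM. Per the labels' protocols, cells were kept in DMEM with 10% serum, which was charcoal-stripped during treatment, amplified cDNA was made into Nextera XT libraries, and single-end reads of 100 bases were sequenced on a NovaSeq. The length of treatment and the strandedness of the libraries are not given in the sources used here. Reads of a gene and of an overlapping or antisense partner can therefore not be told apart.

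The authors deposited whole-number counts per gene symbol, not normalized, for all 18 libraries in a single table of 35238 gene rows. Per the submitters' processing notes, the build was GRCh38 and DESeq2 was among the tools, with no version. The aligner, the counting tool and the gene annotation are not given in the sources used here. Symbols identify the genes in the table, and 28 of them had been turned into dates by spreadsheet software, 22 of which were tested; these are never named. A count was present in at least 1 library for 24982 rows. Total counts ran from 28135967 to 34992442 per library, so that 3 counts, taken as the floor, correspond to 0.086 to 0.107 CPM. The floors come from counts alone, and amplified reads without molecular identifiers are not independent molecules. Intervals of log2 fold changes come from the fit described below and include the spread between libraries of a group. Gene positions come from GENCODE release 29 on GRCh38, matched by symbol for 95.7% of the tested genes.

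The replicate numbers are in the titles, which do not say whether the replicates are separate cultures; p-values measure only the spread between these samples, which may be technical. In every group each pair of replicates differed by more than sampling noise, with a chi-square of 4.59 to 14.17 per gene where noise alone gives about 1, and no library was counted as a copy of another. The labels do not say which vehicle belongs to which compound. DMSO was taken as the vehicle of the small molecules and ethanol as that of DLPC from knowledge of the study, and the other vehicle and both vehicles averaged were run as alternatives.

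The design, the tests, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except for the 5 alternatives given as added below. The tests of the 3 flagged patterns and the groupings of 12 libraries within replicate numbers were also chosen after. Genes were kept by the default rule of edgeR's filterByExpr (a minimum count of 10 in about 3 libraries and a total of 15), which left 14797 genes holding 99.96% of all counts. All 18 libraries entered a single fit with 1 mean per group, TMM scaling and no other covariate. Each comparison was tested with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) and Benjamini-Hochberg adjustment, with a threshold of 0.05, two-sided. The biological coefficient of variation was 7.0%. Over the 10713 genes above 5 CPM the 95% interval of a log2 fold change reached a median of 0.15 to either side in each of the comparisons of a pair of groups.

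There were 4 comparisons of a treatment with its vehicle, 3 between the small molecules at the same dose, 1 between the vehicles, and 3 of the response to DLPC minus the response to a small molecule. A named gene had an adjusted p under 0.05, a mean of at least 1 CPM and all 3 libraries of either group above all 3 of the other, and was among the 10 largest rises or 10 largest falls. The 4 members with the smallest p of each called list, called members of the LRH-1 target list and NR5A2 were added, and the 3 smallest p-values where fewer than 5 genes passed. For the DLPC contrasts the 5 largest differences in each direction were named. Other genes in the text are members of the fixed lists that passed, chosen after their values were seen. Some genes that the rule names are not reported here.

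Fixed lists, 24 in number with 495 of their 547 members tested, were tested in the first 7 of these comparisons with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the 24 lists. They cover LRH-1 targets, bile acid synthesis and transport, cholesterol synthesis and uptake, fatty acid and triglyceride synthesis, LXR targets, fatty acid oxidation and PPAR targets, lipoproteins, phospholipid synthesis and remodelling, glucose metabolism, amino acid response and ATF4 targets, unfolded protein response, NRF2 targets, heat shock, cell cycle, p53 targets, inflammatory signalling, acute phase proteins, xenobiotic metabolism, hepatocyte identity, autophagy and lysosome, mitochondrial mRNAs, nuclear-encoded respiratory chain, ribosomal proteins, and markers of stromal, endothelial and blood cells. Each list was tested again with its correlation estimated from the data: of 168 tests, 71 passed with the preset correlation and 18 with an estimated one. Arbitrary splits of 6 libraries gave up to 14 called lists with the preset correlation (up to 9 where each same-number pair was parted). With an estimated correlation they gave at most 1. The preset correlation may therefore be liberal in these libraries. The splits cannot decide this, since their arms keep part of any difference between the groups. Where pairs are not parted they also carry replicate effects.

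Libraries with the same replicate number deviated together from their group means. The correlations of these deviations over 9911 genes were above 0.1 for all same-number pairs within each comparison (for example 0.37 to 0.50 between DLPC and ethanol) except 1 of 45, at 0.07, which falls in the contrast of DLPC with 6N. A fit with the replicate number as a block, planned as an alternative, had a biological coefficient of variation of 4.4%; its value is given beside a result where it changes a call or moves a count by over 1.5 times, and for the contrast of DLPC with 6N, whose numbers do not all pair the libraries, only among the alternatives. The other alternatives were DESeq2 1.42.0, limma-voom with library weights, DESeq2's size factors, no low-count filter, only the groups compared, fry, and each replicate left out in turn. Removal of the trend with GC content and gene length, alone and with the block, and the block without ethanol replicate 3, were added after the data were seen, as were the calls shared by 6N and 6N-10CA with ethanol as the vehicle of either.

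The tests were tested on simulated data with 14797 genes drawn from the libraries' means and depths, 200 of them changed. For 6N against DMSO with replicate effects, edgeR recovered 23.9%, 67.2% and 78.8% of the genes changed 1.25-fold, 1.5-fold and 2-fold, with 2 false calls among 115; the block recovered 37.3%, 73.1% and 83.3%, with 9 false among 138. For DLPC against ethanol edgeR made 0 false calls among 121. Without replicate effects, edgeR made 12 false calls among 130 for 6N against DMSO, and DESeq2 made 18 among 141; for the contrast of DLPC with 6N the false calls were 7 of 104 and 21 of 133. With no list shifted, camera called 0 of 24 simulated lists. Genes were drawn independently of each other there, so this cannot show how camera does where members of a list vary together. CPM are counts scaled to the same total in every library, with sizes adjusted by TMM, and figures were drawn with matplotlib.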

Results

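Gene expression was profiled in HepG2 liver cells treated with compounds of a study of the nuclear receptor LRH-1, a transcription factor that controls genes of bile acid, cholesterol and steroid metabolism. The small molecules 6N, 10CA and 6N-10CA were each given at 10 µM and are set against DMSO. The phospholipid DLPC, known to bind LRH-1, was given at 100 µM and is set against ethanol. Each of the 6 groups had 3 libraries with total counts of 28135967 to 34992442. Because the doses differ 10 µM to 100 µM, values for DLPC and the small molecules stand side by side without being matched. NR5A2, the gene of LRH-1 (GRCh38 chromosome 1, 200027602 to 200177424), was expressed at a low level in every group, from 3.85 ± 0.69 CPM with DMSO to 4.30 ± 0.63 CPM with 10CA (mean ± SD, n = 3). Its log2 fold change lay between -0.09 and 0.16 in the 8 comparisons of a pair of groups, and it was not called in any. The 95% interval against vehicle was -0.36 to 0.42 for 6N, -0.23 to 0.54 for 10CA, -0.32 to 0.45 for 6N-10CA and -0.37 to 0.42 for DLPC. Log2 fold changes below are given with the SE of the fit, and the largest changes are those among called genes with a mean of at least 1 CPM whose libraries did not overlap between the groups.

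With 6N, genes of cholesterol synthesis and uptake fell as a group. Of 24 measured members, 0 rose and 23 fell, with PMVK the exception (log2 fold change -0.07), and the count was also 23 adjusted over the list alone. HMGCS1, which makes the HMG-CoA used for sterol synthesis (chromosome 5, 43289395 to 43313512), fell from 307.3 ± 19.7 to 170.5 ± 6.69 CPM, a log2 change of -0.85 (SE 0.06). MVD changed by -0.75, LSS, the lanosterol synthase, by -0.69 and FDFT1, the squalene synthase, by -0.58. The list was lower by camera with an adjusted p of 2.185e-58 (5.7e-05 with an estimated correlation), and its median log2 fold change was -0.47.

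Fatty acid synthesis followed the same direction with 6N. Of 22 measured members of the fatty acid and triglyceride synthesis list, 2 rose and 11 fell, against 2 and 14 adjusted over the list alone (adjusted p = 1.065e-22, and 5.7e-05 with an estimated correlation). FASN, the fatty acid synthase, changed by -1.17 (SE 0.10), the desaturases FADS2 and SCD by -0.97 and -0.81, and ACACA by -0.65. SREBF1, which encodes the lipogenic transcription factor SREBP1 (chromosome 17, 17810399 to 17837002), went from 306.5 ± 15.8 to 149.4 ± 11.9 CPM, a change of -1.04 (SE 0.07). The members that rose were the diacylglycerol acyltransferases DGAT1 and DGAT2, at 0.21 and 0.29. In the LXR target list, 3 of 13 members fell (SREBF1, MYLIP at -1.03 and LPCAT3 at -0.39), 0 rose, and 4 fell adjusted over the list alone (adjusted p = 3.758e-09, and 0.00155 with an estimated correlation).

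Genes of xenobiotic metabolism rose with 6N: 5 of 18 measured members passed and 0 fell, against 9 and 0 adjusted over the list alone (adjusted p = 3.342e-10, and 0.00155 with an estimated correlation). CYP1A1, the classic target of the aryl hydrocarbon receptor (chromosome 15, 74719542 to 74725610), rose from 9.97 ± 1.21 to 38.4 ± 2.51 CPM, a log2 change of 1.95 (SE 0.22) or 3.86-fold. CYP3A7 rose by 0.84, GSTA2 by 0.49 and POR, the electron donor of microsomal P450 enzymes, by 0.31. Reads of CYP3A7 and of GSTA2 can be shared with close relatives in their families. Outside the lists the largest rises were CYP24A1, the vitamin D catabolic enzyme, at 1.97 (SE 0.35) from a level of 0.55 ± 0.10 CPM, SEC14L4 at 1.14, CPSF4L at 1.01 and CYB5A at 0.82. The largest fall was IL17B at -1.31. SLC51A, a subunit of the basolateral bile acid exporter, rose by 0.68, the 1 called member of the bile acid list (21 measured; 9 rose adjusted over the list alone and, with the replicate number as a block, 7 rose and 1 fell). That list was higher with an adjusted p of 0.002432 but 0.05057 with an estimated correlation, and 0.01775 with both an estimated correlation and the block.

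The unfolded protein response list was lower with 6N although 0 of 21 members were called. Of these, 7 fell adjusted over the list alone and 9 with the block, among them HSPA5, the ER chaperone BiP, at -0.21 and DNAJB11 at -0.24 (adjusted p = 4.845e-09, and 0.02474 with an estimated correlation). The cell cycle list was higher with 0 of 34 members called and 0 adjusted over the list alone; CDK1 stood at 0.19 and PLK1 at 0.10 (adjusted p = 9.721e-11, but 0.09558 with an estimated correlation). With the block 10 of them rose, and the adjusted p with an estimated correlation was 0.0004506. Among 23 measured LRH-1 targets 0 were called, 2 rose adjusted over the list alone and 2 rose and 2 fell with the block (adjusted p of the list = 0.4232). CYP7A1, the rate-limiting enzyme of bile acid synthesis, had a log2 fold change of 0.39 (SE 0.10; adjusted p = 0.09363), and 0.39 with an adjusted p of 0.000641 with the block.

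In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 169 genes for 6N against DMSO, 44 higher and 125 lower, of which 11 changed over 2-fold, and 7 of 24 lists, 5 of them with an estimated correlation. With the block the count was 551, 198 higher and 353 lower, including all 169. Without DMSO replicate 1 the count was 112, and without 6N replicate 2 it was 111; without 6N replicate 1 the list count was 11. Levels of 6 genes named in the text are plotted by library.

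**Figure D1:**
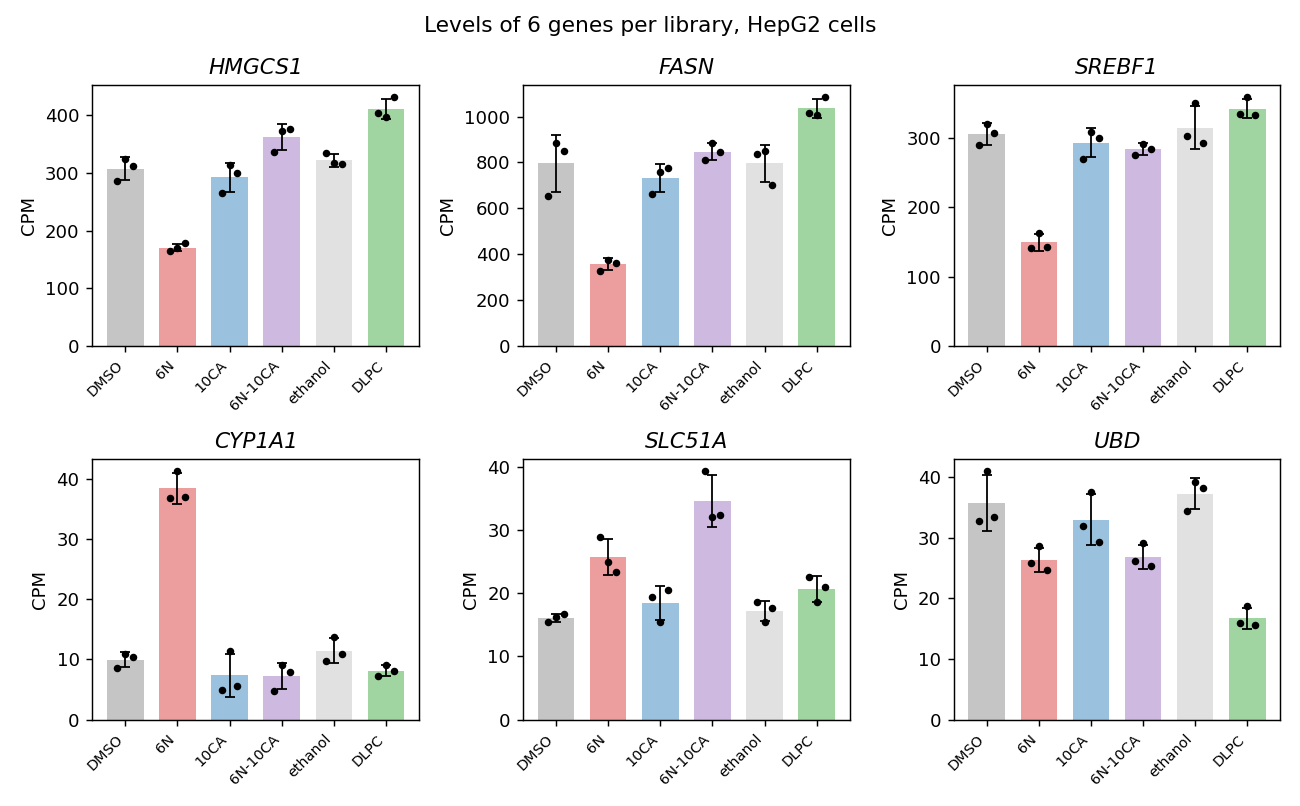
CPM (vertical axes, from 0) of HMGCS1, FASN, SREBF1, CYP1A1, SLC51A and UBD in the 6 groups; points are the 3 libraries of a group, bars the mean and error bars the SD. HMGCS1 averaged 170.5 CPM with 6N and 411.1 CPM with DLPC, and CYP1A1 averaged 38.4 CPM with 6N and 9.97 CPM with DMSO.

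10CA at the same dose left no gene past the threshold. The gene with the smallest p, SIAE, a sialic acid esterase, had a log2 fold change of -0.60 (SE 0.11), from 10.0 ± 0.94 to 6.63 ± 0.76 CPM, and RSL24D1, a ribosome biogenesis factor, one of 0.24 (SE 0.05). ARMCX7P, listed as a pseudogene by its symbol, stood at 2.20 ± 0.23 CPM with DMSO and 0.34 ± 0.44 CPM with 10CA. Members of the cholesterol list leaned lower, with MVD at -0.21 and EBP at -0.19, but 0 rose and 0 fell. Adjusted over the list alone, 3 of 24 fell (adjusted p = 2.543e-06, but 0.6582 with an estimated correlation). The mitochondrial mRNA list had 0 of 13 called and 3 lower adjusted over the list alone, with MT-CO3 at -0.28 (adjusted p = 1.306e-06, but 0.6582 with an estimated correlation). The amino acid response list had 0 of 27 called and 3 higher adjusted over the list alone, with ASNS, asparagine synthetase, at 0.28 and MTHFD2 at 0.20 (adjusted p = 0.001157, but 0.6776 with an estimated correlation). With the block 1 cholesterol gene and 2 mitochondrial mRNAs fell and 3 amino acid response genes rose. The unfolded protein response, cell cycle and respiratory chain lists also passed with the preset correlation, for 6 lists in all, and 0 passed with an estimated one.

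By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 genes were called for 10CA against DMSO, with 1033 at an unadjusted p under 0.05 and a smallest adjusted p of 0.5652. If no gene changed, a share of at most about 0.05 of the 14797 tested genes would have such an unadjusted p, here and in the counts below. The spread of this fit includes effects that libraries of the same replicate number share (7.0%, against 4.4% with the block). Such effects cancel between groups, so the share may be under 0.05 and the test conservative. DESeq2 called 16, limma-voom 0, and the fit with the block 32, of which 19 were higher and 13 lower. SIAE, RSL24D1, ARMCX7P, EBP, MTHFD2, PSAT1, ASNS and MT-CO3 were called with the block, with SIAE at an adjusted p of 0.01872. Without 10CA replicate 1 the count was 1. The per-gene 95% interval lay within 0.5 log2 units (1.41-fold) of no change for 97.2% of the 10713 genes above 5 CPM. This share was 95.5% for 6N and 96.1% for 6N-10CA against DMSO, 94.7% for DLPC against ethanol and 97.3% for ethanol against DMSO. It therefore separates these comparisons little.

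With 6N-10CA the bile acid exporter subunit gene SLC51A (chromosome 3, 196211487 to 196243178) rose from 16.1 ± 0.66 to 34.6 ± 4.13 CPM, a log2 change of 1.11 (SE 0.11). KNG1, encoding kininogen, rose by 0.75, HAMP, encoding the iron hormone hepcidin, by 0.62, the prolyl hydroxylase gene P4HA1 by 0.64, and CYB5A by 0.58. PLIN2, which coats lipid droplets, rose by 0.40 and AGPAT2, of triglyceride synthesis, by 0.52. Falls included the tight junction gene CLDN2 at -0.72, AGR2 at -0.70, the hedgehog ligand IHH at -0.63, SPP1, encoding osteopontin, at -0.52 (SE 0.06), and the glycerol phosphate dehydrogenase GPD1 at -0.44.

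Several lipid lists leaned higher with 6N-10CA, but none passed with an estimated correlation. Fry, an alternative list test, kept 6 of the 8 lists called in this comparison. In the cholesterol list 0 of 24 were called and 7 were higher adjusted over the list alone, 9 with the block, with HMGCS1 at 0.24 and FDFT1 at 0.21 (adjusted p = 5.018e-08, but 0.08323 with an estimated correlation). In the fatty acid and triglyceride synthesis list 1 of 22 rose, AGPAT2, and 8 adjusted over the list alone (adjusted p = 1.266e-05, but 0.06916 with an estimated correlation); with the block 7 rose and the adjusted p with an estimated correlation was 0.02098. In the fatty acid oxidation list 2 of 24 rose, PLIN2 and ACADM, and 6 adjusted over the list alone or with the block (adjusted p = 1.329e-05, but 0.08323 with an estimated correlation). The unfolded protein response list was lower with 0 of 21 called, 3 lower adjusted over the list alone and 11 with the block, with XBP1 at -0.17 (adjusted p = 2.372e-07, but 0.08323 with an estimated correlation; 0.02098 with the block and an estimated correlation). The bile acid list, with 1 of 21 risen and 5 adjusted over the list alone or with the block, was higher with an adjusted p of 0.04719 (0.2014 with an estimated correlation, and 0.06967 with the block). The xenobiotic list was also higher than with DMSO, with 0 of 18 called, and 6 higher and 1 lower adjusted over the list alone. With the block 5 rose and 1 fell (adjusted p of camera without the block = 0.0182, but 0.2014 with an estimated correlation). The lipoprotein and autophagy lists passed with the preset correlation as well. The LRH-1 target CYP7A1 had a log2 fold change of 0.43 (SE 0.10; adjusted p = 0.09062), and 0.0004963 with the block.

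The count for 6N-10CA against DMSO was 39 genes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 21 higher and 18 lower, and 8 lists, 0 of them with an estimated correlation; with the block it was 562 genes, 249 higher and 313 lower. Each library left out lowered it by over 1.5 times: it was 19, 20 and 12 without DMSO replicate 1, 2 and 3, and 23, 16 and 18 without 6N-10CA replicate 1, 2 and 3.

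With DLPC the cholesterol genes rose. Of 24 measured members 10 rose and 0 fell, against 21 adjusted over the list alone and 18 with the block. MVD rose by 0.42, DHCR7, the last enzyme of cholesterol synthesis, by 0.43, HMGCS1 by 0.35 (from 322.2 ± 11.2 to 411.1 ± 17.7 CPM), and LSS by 0.31. The list was higher with an adjusted p of 4.955e-20 (0.005151 with an estimated correlation). Of 22 members of the fatty acid and triglyceride synthesis list 3 rose and 0 fell, against 13 adjusted over the list alone and 12 with the block. They were the acetyl-CoA producers ACSS2 and ACLY, at 0.51 and 0.33, and SCD, at 0.32 (adjusted p = 1.05e-08, and 0.005151 with an estimated correlation). FASN stood at 0.38 (SE 0.09; adjusted p = 0.05912) and was called with the block at 0.002386. CYP19A1, the aromatase and an LRH-1 target (chromosome 15, 51208057 to 51338610), rose from 50.8 ± 5.85 to 70.8 ± 7.93 CPM, a change of 0.48 (SE 0.08), and was the 1 called member of the 23 LRH-1 targets, also adjusted over the list alone. With the block 3 of the targets rose and 1 fell. The list's adjusted p was 0.05994 (0.4056 with an estimated correlation), and 0.02774 with the block (0.1608 with the block and an estimated correlation).

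Inflammatory genes fell with DLPC: 4 of 12 measured members fell and 0 rose, against 8 fallen adjusted over the list alone and 7 with the block (adjusted p = 3.032e-09, and 0.0005993 with an estimated correlation). The NF-kB subunit gene RELB changed by -0.85 (SE 0.13), NFKBIZ by -0.50, and ICAM1, an adhesion molecule, by -0.36. The chemokine gene CXCL2 lay near the floor, at 0.47 ± 0.05 CPM with ethanol and 0.03 ± 0.05 CPM with DLPC. Among named genes, which have a mean of at least 1 CPM, the largest fall was UBD, a ubiquitin-like modifier induced by inflammatory cytokines (chromosome 6, 29555515 to 29559925), from 37.3 ± 2.5 to 16.7 ± 1.73 CPM, a change of -1.16 (SE 0.11). PLA2G2A, a secreted phospholipase, followed at -0.95, TAGLN at -0.83 and SPINK1 at -0.77. In the acute phase list SERPINA3, HP and HPX fell by 0.42, 0.39 and 0.41 on the log2 scale and SAA4 rose by 0.35, 4 of 19, also adjusted over the list alone. The count was 6 with the block (adjusted p = 0.01504, but 0.4056 with an estimated correlation).

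The largest rises with DLPC were MNX1 at 0.87, from 5.65 ± 0.90 to 10.3 ± 0.97 CPM, then CARM1, a histone arginine methyltransferase, at 0.86, RNF19B at 0.85, TADA2B at 0.82 and BRD1 at 0.82, and others of the 10 largest include SLC6A8, SDK1, PAPD7 and C2orf72. Against DMSO in place of ethanol the median log2 fold change of these 10 genes was 0.18 rather than 0.81, TADA2B stood at -0.05, and 1 of the 10 was called. The same change of vehicle left the median of the cholesterol list at 0.24, against 0.23.

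By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 154 genes were called for DLPC against ethanol, 93 higher and 61 lower, and 15 lists, 3 of them with an estimated correlation. With the block 997 genes were called, 533 higher and 464 lower. The gene count was 87, 56 and 83 without ethanol replicate 1, 2 and 3, 59 without DLPC replicate 1 and 70 without DLPC replicate 3, and the list count was 9 without ethanol replicate 2. In the limma-voom and DESeq2 fits it was 310 and 380.

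**Figure D2:**
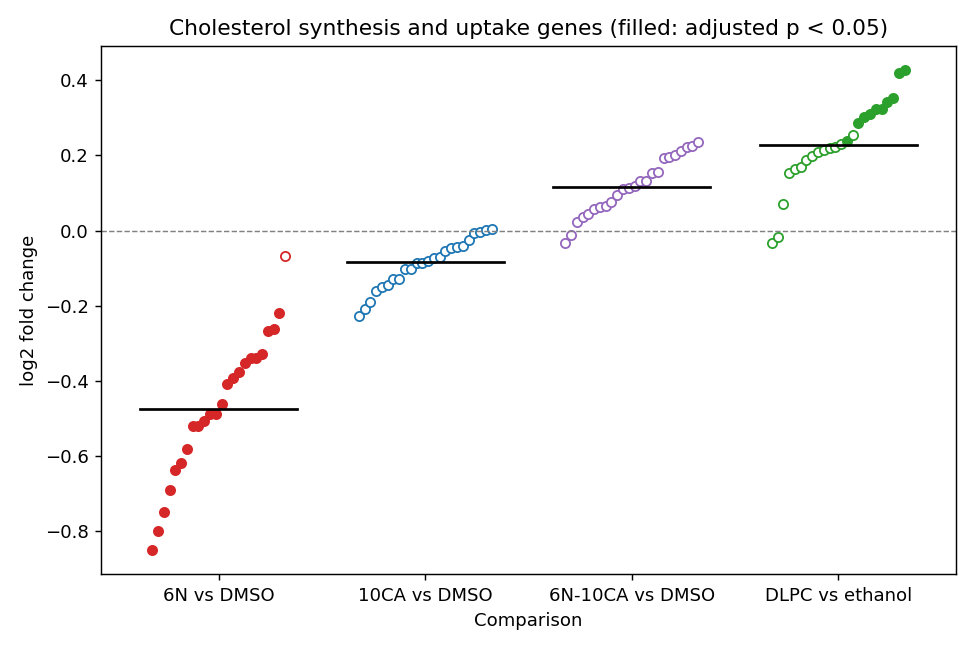
Log2 fold change (vertical axis) of the 24 measured cholesterol synthesis and uptake genes in each treatment against its vehicle (horizontal axis), sorted by value within a comparison; filled points passed the adjusted threshold and lines are medians. The medians were -0.47 with 6N, -0.08 with 10CA, 0.11 with 6N-10CA and 0.23 with DLPC.

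The vehicles themselves were compared as a background. FGA, a fibrinogen chain, stood at -0.21 (SE 0.04) with ethanol against DMSO, PCSK6 at -0.54 and TADA2B at -0.88, each with an adjusted p of 0.3668. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 0 genes were called, with 479 at an unadjusted p under 0.05. DESeq2 called 12, limma-voom 0, and the fit with the block 18, 6 higher and 12 lower, FGA, PCSK6 and TADA2B among them. Without ethanol replicate 3 the count was 7.

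At the matched dose of 10 µM, 10CA and 6N differed most in lipid synthesis and xenobiotic genes. With 10CA, 19 of 24 cholesterol genes were higher than with 6N and 0 lower (22 adjusted over the list alone), with HMGCS1 at 0.78 (SE 0.06), MVD at 0.54 and LSS at 0.53 (adjusted p = 4.471e-35, and 0.0006687 with an estimated correlation). Of the fatty acid and triglyceride synthesis genes 11 of 22 were higher and 2 lower, against 15 and 2 adjusted over the list alone, with FASN at 1.05 and SREBF1 at 0.97 higher and the DGAT1 and DGAT2 pair lower (adjusted p = 1.785e-17, and 0.0004352 with an estimated correlation). LXR targets MYLIP, SREBF1 and LPCAT3 were higher, 3 of 13, against 5 adjusted over the list alone, and 0 were lower (adjusted p = 2.493e-07, and 0.00344 with an estimated correlation). Xenobiotic genes were lower, 7 of 18 against 9 adjusted over the list alone, with CYP1A1 at -2.39 (SE 0.23), CYP3A7 at -0.89 and GSTA2 at -0.74 (adjusted p = 5.883e-10, and 0.002181 with an estimated correlation).

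Bile acid genes were lower with 10CA than with 6N in 5 of 21 cases, also adjusted over the list alone, among them CYP7A1 (chromosome 8, 58490178 to 58500236) at -0.49 (95% interval -0.71 to -0.28), SLC51A at -0.48 and CYP27A1 at -0.20. The adjusted p of the list was 0.003999, but 0.07053 with an estimated correlation and 0.02437 with the block and an estimated correlation. CYP7A1 averaged 20.9 ± 1.59 CPM with 6N and 14.9 ± 1.23 CPM with 10CA. SULT2A1, a bile acid and steroid sulfotransferase, was lower at -0.28 (95% interval -0.39 to -0.17), making 2 of 23 LRH-1 targets lower and 0 higher, against 3 and 0 adjusted over the list alone. With the block 4 were lower and 1 higher. NR0B2, the LRH-1 target encoding the repressor SHP, differed by -0.27 (95% interval -0.58 to 0.05; adjusted p = 0.4703), and was called with the block at 0.008104. Of the markers of other cell types, PDGFRB and LYZ were higher, at 0.62 and 0.32, 2 of 11, also adjusted over the list alone. The cell cycle list was lower with 0 of 34 called, 2 adjusted over the list alone and 7 with the block (adjusted p = 0.0008252, but 0.5235 with an estimated correlation; 0.01284 with the block and an estimated correlation). The acute phase list had 1 of 19 higher and 4 lower, against 3 and 5 adjusted over the list alone or with the block (adjusted p = 0.04753, but 0.5479 with an estimated correlation and 0.1334 with the block).

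For 10CA against 6N 253 genes were called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 155 higher and 98 lower, and 13 lists, 4 of them with an estimated correlation. With the block 1133 genes were called, 612 higher and 521 lower. The gene count was 148 without 6N replicate 1, 157 without 6N replicate 2 and 141 without 10CA replicate 3.

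6N-10CA differed from 6N in the cholesterol, fatty acid and LXR lists. Of the cholesterol genes 23 of 24 were higher with 6N-10CA and 0 lower, also adjusted over the list alone, with HMGCS1 at 1.09 (SE 0.06), LSS at 0.91 and MVD at 0.94 (adjusted p = 3.872e-54, and 7.922e-05 with an estimated correlation). Of the fatty acid and triglyceride synthesis genes 15 of 22 were higher and 1 lower, against 17 and 2 adjusted over the list alone, with FASN at 1.26, FADS2 at 1.15, ACSS2 at 0.98 and SREBF1 at 0.93 (adjusted p = 9.095e-26, and 5.843e-05 with an estimated correlation). LXR targets were higher in 4 of 13 cases, against 5 adjusted over the list alone, with PLTP at 0.26 added to the 3 named for 10CA (adjusted p = 2.077e-08, and 0.002331 with an estimated correlation). CYP1A1 was lower at -2.41 (SE 0.23), averaging 7.19 ± 2.19 CPM with 6N-10CA, and the xenobiotic list had 2 of 18 lower, against 5 adjusted over the list alone and, with the block, 5 lower and 1 higher (adjusted p = 0.001405, but 0.09919 with an estimated correlation). FABP1, the liver fatty acid binding protein gene, was higher at 0.81 and ACSL1 at 0.59, among 4 of 24 fatty acid oxidation genes. The count was 5 adjusted over the list alone and 7 with the block (adjusted p = 0.0004845, but 0.1567 with an estimated correlation). In the cell cycle list PLK1 and CDC20 were lower, each at -0.21, 2 of 34 against 9 adjusted over the list alone and 15 with the block (adjusted p = 1.638e-07, but 0.2515 with an estimated correlation; 0.002409 with the block and an estimated correlation).

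CYP7A1 did not pass between 6N-10CA and 6N, with a difference of 0.05 (95% interval -0.17 to 0.26), and NR0B2 differed by 0.17 (95% interval -0.15 to 0.48). The direct comparison of 6N-10CA with 10CA for CYP7A1 is given below. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 242 genes were called, 166 higher and 76 lower, and 8 lists, 3 of them with an estimated correlation. With the block 1231 genes were called, 577 higher and 654 lower. Without 6N replicate 1 the gene count was 155, without 6N replicate 2 it was 138, and without 6N-10CA replicate 3 it was 143.

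Compared with 10CA, 6N-10CA gave higher levels of 29 genes and lower levels of 5. SLC51A was higher by 0.91 (SE 0.11), HAMP by 0.81, KNG1 by 0.80, GNMT, the glycine methyltransferase of liver, by 0.68, and CYP7A1 by 0.54 (95% interval 0.32 to 0.75). Of the cholesterol genes 5 of 24 were higher and 0 lower, against 20 adjusted over the list alone and 15 with the block, with MVD at 0.40 and LSS at 0.39 (adjusted p = 4.884e-22, and 0.009703 with an estimated correlation). Of the fatty acid and triglyceride synthesis genes 2 of 22 were higher, ACSS2 and FADS1 at 0.41 and 0.23, and 8 adjusted over the list alone or with the block (adjusted p = 1.324e-07, and 0.009703 with an estimated correlation). In the xenobiotic list GSTA2, CYP3A7 and CYP3A5 were higher, at 0.52, 0.62 and 0.57, and the drug exporter ABCB1 was lower at -0.31. That made 3 higher and 1 lower of 18, against 7 and 1 adjusted over the list alone or with the block (adjusted p = 6.272e-05, and 0.03626 with an estimated correlation; 0.07487 with the block and an estimated correlation). The acute phase list had 2 of 19 higher, HAMP and ORM1, against 5 adjusted over the list alone and 6 with the block (adjusted p = 0.0001209, but 0.1592 with an estimated correlation). The bile acid list had 2 of 21 higher, CYP7A1 and SLC51A, against 5 adjusted over the list alone (adjusted p = 0.009162, but 0.1592 with an estimated correlation). CYP7A1 was the 1 called LRH-1 target of 23, with 3 adjusted over the list alone and 4 with the block. SPP1 was lower at -0.38 and ARSI at -0.38.

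In all 34 genes were called for 6N-10CA against 10CA by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 29 higher and 5 lower, and 14 lists, 3 of them with an estimated correlation. With the block 349 genes were called, 207 higher and 142 lower. The gene count was 14 without 10CA replicate 3 and 16 without 6N-10CA replicate 1, and the list count was 6 without 6N-10CA replicate 1.

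The responses were also compared over all 14797 genes, in 6 relations of log2 fold changes; genes are not independent replicates, so these correlations describe the libraries and carry no p-value. Among the small molecules, which share the DMSO libraries, Pearson's r was 0.39 between 6N and 10CA, 0.38 between 6N and 6N-10CA and 0.41 between 10CA and 6N-10CA (Spearman's rho 0.30, 0.29 and 0.43), where unchanged groups simulated against the same vehicle gave 0.50, 0.49 and 0.50. The covariance was 0.0223, 0.0221 and 0.0233, against simulated values of 0.0233, 0.0231 and 0.0231. Among the 10686 genes with a mean of at least 5 CPM r was 0.17, 0.23 and 0.48, and the covariance was 0.00222, 0.00358 and 0.00562, against simulated values of 0.00489, 0.00481 and 0.0048. The simulation had no replicate effects and took its spread from the fit without the block (7.0%, against 4.4% with it). Replicate effects that all groups share cancel in the data between a group and its vehicle. The simulated r and covariance may therefore be higher than unchanged groups would give. DLPC, which shares no library with the small molecules, had r of -0.01 with 6N, 0.05 with 10CA and 0.13 with 6N-10CA (rho -0.06, 0.11 and 0.20), against a simulated 0.00 with an SD of 0.024, 0.023 and 0.023. Among genes of at least 5 CPM these r were -0.05, 0.26 and 0.33. The simulated genes were drawn independently of each other, so the simulated SD does not cover genes that vary together between libraries. Among genes called for both 6N and 6N-10CA 8 were higher in each, where independent lists would share 0.06, and 5 lower, where they would share 0.15, and 1 went opposite ways (MAP1B, at -0.26 with 6N and 0.34 with 6N-10CA, named after its values were seen). The shared rises included SLC51A, CYB5A, KNG1 and STK32C, and the shared falls AGR2, ARSI and SIAE. With ethanol in place of DMSO for 6N alone, so that no vehicle library was shared, 6 rises and 5 falls were shared, and with ethanol for 6N-10CA alone 6 and 7. Of the 13 genes shared against DMSO, 10 and 9 remained. Without the block DLPC and 6N-10CA shared 2 rises and 6 falls, against 0.13 and 0.07 for independent lists, with 0 opposite, and DLPC and 6N shared 2 and 6, against 0.28 and 0.52, with 21 opposite. With the block, DLPC and 6N-10CA shared 90 rises and 97 falls, where independent lists would share 9.0 and 9.8, and 18 genes went opposite ways. DLPC and 6N shared 22 and 44, against 7.1 and 11.1, with 107 opposite, and 6N and 6N-10CA shared 54 and 72, against 3.3 and 7.5, with 33 opposite. The pairs with 10CA, called for 32 genes, shared 3 rises and 7 falls with 6N, 10 and 4 with 6N-10CA and 7 and 2 with DLPC, with 1, 1 and 4 opposite. Independent lists would share 0.3 and 0.3, 0.3 and 0.3, and 0.7 and 0.4. The small molecules share the DMSO libraries, which can add shared calls among their own pairs. Ethanol as the vehicle was not tried with the block for these shared counts.

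The response to DLPC was also set against that to each small molecule, at unlike doses. Compared with 6N, FASN differed by 1.55 (SE 0.13), IL17B by 1.78 and C6orf223 by 2.09 toward higher with DLPC, and CYP1A1 by -2.44, TAGLN by -0.80, the urea cycle gene OTC by -0.78 and UBD by -0.72 toward lower. From 10CA it differed by 0.65 for ACSS2, 0.63 for MVD and 0.55 for DHCR7, and by -1.05 for UBD, -0.98 for PLA2G2A, -0.92 for RELB and -0.51 for ICAM1. From 6N-10CA it differed by 1.43 for TADA2B and 0.98 for C2orf72, and by -0.55 for the kinase gene STK32C. With ethanol against DMSO TADA2B stood at -0.88 and C2orf72 at -0.54, and with DLPC against DMSO at -0.05 and 0.15. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment of these differences, 180 genes were called for DLPC against 6N, 133 higher and 47 lower. There were 16 for DLPC against 10CA, 10 higher and 6 lower, and 10 for DLPC against 6N-10CA, 9 higher and 1 lower. With the block the contrasts with 10CA and 6N-10CA gave 250 and 216. The count of 180 was 95 without DMSO replicate 1, 104 without ethanol replicate 2 and 103 without DLPC replicate 1. The count of 16 was 3, 5 and 6 without DMSO replicate 1, 2 and 3, 7, 9 and 3 without 10CA replicate 1, 2 and 3, 3 and 9 without ethanol replicate 2 and 3, and 4, 3 and 10 without DLPC replicate 1, 2 and 3. The count of 10 was 1, 3 and 18 without DMSO replicate 1, 2 and 3, 1, 1 and 14 without 6N-10CA replicate 1, 2 and 3, 0, 0 and 25 without ethanol replicate 1, 2 and 3, and 1, 0 and 0 without DLPC replicate 1, 2 and 3.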

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

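The tests of the 3 patterns weighed here were chosen after the results were seen; the splits of the libraries were chosen before, except the groupings of 12 libraries within replicate numbers, with or without the limit on whole groups, chosen after.

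Responses that differ between DLPC and a small molecule were picked out by a test of the difference itself. There were 180 such genes for DLPC and 6N, 16 for DLPC and 10CA and 10 for DLPC and 6N-10CA. In 21 genes DLPC and 6N were each called, in opposite directions, with the difference also called; all 21 were higher with DLPC and lower with 6N. Of these, 10 belong to the cholesterol list (among them ACAT2, DHCR7, FDFT1, HMGCS1, LSS, MSMO1, MVD and STARD4), and the others include the fatty acid genes ACLY, ACSL3, ACSL4, ACSS2 and SCD, and IL17B and UCP2. HMGCS1, for example, stood at 0.35 with DLPC and -0.85 with 6N, a difference of 1.20 (SE 0.09; adjusted p = 1.487e-07 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The dose of DLPC was 100 µM and that of 6N 10 µM.

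Cholesterol genes were lower with 6N than with DMSO, with a median log2 fold change of -0.473 over 24 genes, and 23 called. A trend with GC content or gene length as the whole cause is argued against by the median after removal of that trend in the fit with the block, -0.480, against -0.475 before. DMSO libraries standing apart are argued against by ethanol as the control, which gave -0.469 with 23 called. Treatment with 6N stays open as a biological explanation, untested beyond these libraries. The 10 splits of the 6 libraries are too few for a share under 0.05. The real split called 169 genes and the highest other 0, but the arms of the other splits mix both groups. Mixing widens their spread and favours counts near 0.

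The 10 largest rises with DLPC against ethanol had a median log2 fold change of 0.807, 0.814 with the block and 0.807 with the block after removal of the trend with GC content and length, which argues against such a trend as the whole cause. Ethanol libraries standing apart remain a candidate explanation, since the median with DMSO as the control was 0.178, or 22% of 0.807, where the largest falls with DLPC and the largest changes with 6N and 6N-10CA, chosen in the same way, left 85% to 109% under the other vehicle. Of the 10 genes 9 were below DMSO in the ethanol libraries, but edgeR's quasi-likelihood test called none of them for ethanol against DMSO (adjusted p = 0.3668 to 1), and 2 with the block. The genes also varied together in the 12 libraries outside the comparison, with a mean pairwise correlation of 0.69 where 999 random sets of genes had a median of -0.02 and a maximum of 0.29. These sets were matched on mean expression only, and the replicate number was not removed. Variation that libraries of the same number share cancels between DLPC and ethanol by design, since each group holds 1 library of each number. The median with the block, 0.814, was therefore bound to lie near 0.807 and decides nothing here. Other variation between libraries that these genes share may account for part of the rise, which this correlation cannot decide. A response to DLPC stays open as well, and 1 gene of the 10 was called against either vehicle.

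Cholesterol genes were higher with DLPC than with ethanol, with a median log2 fold change of 0.226. After removal of the GC and length trend in the fit with the block the median was 0.248, against 0.227 before, which argues against that trend as the whole cause. With DMSO as the control it was 0.235, which argues against ethanol libraries standing apart. Treatment with DLPC, at its higher dose, stays open and untested beyond these libraries. The 10 splits of these 6 libraries are too few for a share under 0.05. The real split called 154 genes and the highest other 0, but the other splits again mix both groups in each arm, which favours counts near 0.

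For the other comparisons of a pair of groups the 10 splits are likewise too few for a share under 0.05, and the other splits mix both groups in each arm. The real split and the highest other called 39 and 0 genes for 6N-10CA against DMSO, 242 and 0 for 6N-10CA against 6N, 34 and 0 for 6N-10CA against 10CA, 253 and 0 for 10CA against 6N, 0 and 1 for 10CA against DMSO, and 0 and 1 for ethanol against DMSO. The zeros of the real splits are counts of edgeR's quasi-likelihood test; for 10CA against DMSO 1033 genes had an unadjusted p under 0.05 and DESeq2 and limma-voom called 16 and 0, and for ethanol against DMSO these were 479, 12 and 0. With the block, the other 3 splits that part each pair of same-number libraries called at most 1 gene (ethanol against DMSO, real split 18) and 0 in the rest.

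For lists with the preset correlation, the real split and the highest other called 7 and 14 for 6N against DMSO, 6 and 12 for 10CA against DMSO, 8 and 12 for 6N-10CA against DMSO, 15 and 14 for DLPC against ethanol, 8 and 13 for 6N-10CA against 6N, 14 and 12 for 6N-10CA against 10CA and 13 and 12 for 10CA against 6N, again too few splits for a share under 0.05. Among the other 3 splits that part each pair of same-number libraries the highest list counts in this order were 9, 1, 5, 5, 6, 3 and 5. With an estimated correlation the same pairs of counts were 5 and 0, 0 and 0, 0 and 0, 3 and 0, 3 and 1, 3 and 0, and 4 and 0. The arms of the other splits mix both groups for lists too, and keep part of any difference between the groups.

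For the contrasts of responses, 33 other groupings of the 12 libraries were drawn without regard to replicate number. Some of these place all 3 libraries of a treatment on one side of the contrast, so they carry its effect and give no value without an effect. For DLPC and 6N 2 of 34 groupings gave as many genes as the real 180, the other, with 250, having all 3 6N libraries on one side, so this count leaves chance open. The real grouping gave 16 genes and the highest other 1 for DLPC and 10CA (1 of 34 as large), and 10 and 5 for DLPC and 6N-10CA (1 of 34). A further 49 groupings kept 1 library of each number in each arm. For DLPC and 10CA 2 of 50 were as large, the other with 45 genes, and with the block 4 of 50, up to 505 against 250; the grouping with 45 and 505 genes set all DLPC libraries against all DMSO libraries, so this count leaves chance open too. For DLPC and 6N-10CA the highest of these others gave 3 (1 of 50), or 160 against 216 with the block (1 of 50).

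In 33 groupings for each contrast that kept the numbers apart and left no group whole on one side, the highest other split gave 1 gene against 180 for DLPC and 6N, 1 against 16 for DLPC and 10CA and 0 against 10 for DLPC and 6N-10CA (1 of 34 as large in each). The arms of such groupings mix treatments, which widens their spread and favours counts near 0, so they do not exclude chance. The planned groupings alone would exclude it for 10CA and 6N-10CA, but they mix treatments too and ignore the replicate numbers, and chance is left open for all 3 contrasts. The 16 genes for 10CA fell to 3 without DMSO replicate 1, 10CA replicate 3, ethanol replicate 2 or DLPC replicate 2, and the 10 for 6N-10CA to 0 or 1 without DMSO replicate 1, 6N-10CA replicate 1 or 2, ethanol replicate 1 or 2, or any DLPC replicate.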

How the results depend on the processing

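Alternatives that removed the GC and length trend, alone or with the block, the block without ethanol replicate 3, and ethanol as the vehicle of 6N or of 6N-10CA for their shared calls (11 and 13 against 13) were chosen after the data were seen; the others were planned. DESeq2's size factors in place of TMM moved no count of genes by over 1.5 times. Where not stated otherwise the cause of a moved count was not tested. Comparisons follow in the order 6N, 10CA and 6N-10CA against DMSO, DLPC against ethanol, 6N-10CA against 6N and against 10CA, 10CA against 6N, and ethanol against DMSO, whose counts were 169, 0, 39, 154, 242, 34, 253 and 0, then the response to DLPC minus that to 6N, 10CA and 6N-10CA, with 180, 16 and 10. Beside the counts of 0 by edgeR's quasi-likelihood test, 1033 genes for 10CA and 479 for ethanol, both against DMSO, had an unadjusted p under 0.05.

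With the replicate block the counts were 551, 32, 562, 997, 1231, 349, 1133 and 18, then 938, 250 and 216; the first of these contrasts holds the pair of libraries correlated at 0.07, so its numbers pair the libraries least. With the block and the GC and length trend removed they were 803, 53, 749, 1261, 1516, 518, 1179 and 34, then 1189, 380 and 309. With that trend removed and no block, 6N-10CA against DMSO gave 96, 6N-10CA against 10CA 79, and the contrasts with 10CA and 6N-10CA 42 and 19. With the block but without ethanol replicate 3, DLPC against ethanol gave 516, ethanol against DMSO 33, and the contrasts 640, 209 and 164.

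DESeq2 gave 16, 173, 380, 519, 120, 494 and 12 from 10CA against DMSO onward, then 346, 91 and 77. With no low-count filter these were 20, 126, 329, 403, 154, 423 and 37, then 325, 95 and 91. Limma-voom gave 91 for 6N-10CA against DMSO, 310 for DLPC against ethanol, 81 for 6N-10CA against 10CA, 419 for 10CA against 6N, and 54 and 21 for the last contrasts. Fitting only the groups compared, which leaves fewer libraries to estimate the spread, gave 13 for 6N-10CA against DMSO, 109 against 6N, 10 against 10CA and 112 for 10CA against 6N. With the other vehicle the counts were 265 for 6N, 63 for 6N-10CA and 380 for DLPC, and with both averaged, which adds libraries, 270, 129 and 541. Of the 169, 39 and 154 genes called against the first vehicle, 143, 25 and 106 were also called against the other. With both averaged 162, 36 and 142 of them were called.

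Leaving out each replicate, which also leaves fewer libraries, gave 111 to 149, 0 to 1, 12 to 23, 56 to 118, 138 to 235, 14 to 28, 141 to 338 and 0 to 7 genes, then 95 to 194, 3 to 11 and 0 to 25, the lowest of the last without ethanol replicate 1 or 2 or DLPC replicate 2 or 3. List counts in order were 7 to 11, 5 to 9, 6 to 9, 9 to 19, 6 to 9, 6 to 15 and 10 to 13. NR5A2 was called in none of the alternatives.

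An estimated correlation left 0 lists of 6 for 10CA and 0 of 8 for 6N-10CA against DMSO, 3 of 15 for DLPC, 3 of 8 for 6N-10CA against 6N, 3 of 14 against 10CA and 4 of 13 for 10CA against 6N. Fry, which asks whether a list moves on balance, called 8 lists for 6N, 0 for 10CA and 6 for 6N-10CA against DMSO. It called 5 for DLPC, 6 for 6N-10CA against 6N, 5 for 6N-10CA against 10CA and 7 for 10CA against 6N. The block changed 16 of 168 list calls with the preset correlation and 9 with an estimated one, and no others. Those not given with their comparison passed with the block for 6N (glucose metabolism 0.01604, amino acid response 0.008991, inflammatory signalling 0.01732), 10CA (fatty acid oxidation 0.04688, autophagy 0.03384, ribosomal proteins 0.01305), 6N-10CA (glucose metabolism 0.02633, acute phase 0.03958), DLPC (unfolded protein response 0.04959, hepatocyte identity 0.007777), 6N-10CA against 6N (heat shock 0.02006, p53 targets 0.03103) and against 10CA (hepatocyte identity 0.005693), as adjusted p of camera; none of these passed with the block and an estimated correlation (adjusted p = 0.1023 to 0.6022). Among genes of at least 5 CPM the correlations of responses were 0.17 for 6N and 10CA, 0.23 for 6N and 6N-10CA, 0.48 for 10CA and 6N-10CA, -0.05 for DLPC and 6N, 0.26 for DLPC and 10CA and 0.33 for DLPC and 6N-10CA. Without a replicate they ran from 0.39 to 0.44, 0.36 to 0.46, 0.42 to 0.47, -0.03 to 0.01, 0.02 to 0.06 and 0.10 to 0.11.

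With DMSO in place of ethanol, 3 of the 154 genes called for DLPC changed sign. Among the results named in the text those that changed sign were the correlation of DLPC and 6N without replicate 3, at 0.01, TADA2B for DLPC against DMSO, at -0.054, and the list ribosomal proteins, 10CA vs 6N, which turned toward higher without 6N replicate 1. Its adjusted p was then 0.9624, and without each other replicate it ran from 7.84e-06 to 0.7463, against 0.02131 with all. Of 406 named gene results, the block left 290 on the same side of the threshold and moved 116 past it, and DESeq2 left 341, moved 56 past it and lost 9. Total counts of 28135967 to 34992442 limit genes near 0.1 CPM, such as CXCL2 with DLPC, to a few counts per library.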

Other observations

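The lists below were fixed in advance, their grouping was chosen after the results were seen, and no explanation is tested.

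Of the 24 lists, 18 passed in no comparison with an estimated correlation. The list of hepatocyte identity genes, which covers secreted liver proteins and liver transcription factors, had 0 of 24 members called by edgeR's quasi-likelihood test in any of the 7 comparisons with list tests (9 had an unadjusted p under 0.05 in at least 1, DESeq2 called 2, limma-voom 1 and the fit with the block 10), and a smallest adjusted p of 0.06017. Over 7 comparisons an unadjusted p under 0.05 in at least 1 is common by chance, for this list and those below. The list of phospholipid synthesis and remodelling had a smallest adjusted p of 0.3613, although 5 of its 27 measured members were called in at least 1 comparison, among them LPCAT3, which remodels membrane phospholipids, at -0.39 with 6N. Stromal, endothelial and blood cell markers gave a smallest adjusted p of 0.1553 with 2 of 11 members called. Lipoprotein genes had 2 of 18 members called, LCAT and PLTP, and a smallest adjusted p of 0.002057 (0.4056 with an estimated correlation). Among 26 autophagy and lysosome genes 3 were called, with CTSB at 0.33, LIPA at -0.21 and WIPI1 at -0.39 for 6N against DMSO (smallest adjusted p of the list over comparisons = 0.01884, and 0.2014 with an estimated correlation). Of the 20 p53 targets, 13 heat shock genes, 30 nuclear-encoded respiratory chain genes and 30 ribosomal protein genes 0 were called in any comparison, with smallest adjusted p of 0.01504, 0.01617, 0.0001486 and 0.01504 for the lists, and 0.4056, 0.4056, 0.5235 and 0.632 with an estimated correlation. In the same order 8, 5, 9 and 0 of these genes had an unadjusted p under 0.05 in at least 1 comparison, DESeq2 called 2, 0, 0 and 0, limma-voom 2, 0, 0 and 0, and the fit with the block 7, 8, 4 and 0. The p53 target list was lower for DLPC against ethanol, where its adjusted p with the block and an estimated correlation was 0.0173. Glucose metabolism and NRF2 targets each had 2 members called, of 27 and 21 (smallest adjusted p = 0.0001107 and 0.01229, and 0.4056 for each with an estimated correlation). Amino acid response genes had 3 of 27 called, with TRIB3, a stress-induced pseudokinase, at -0.24 with 6N (smallest adjusted p = 0.001157, and 0.4056 with an estimated correlation).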
